A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

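RNA was sequenced from 18 polyA libraries, 3 in each of 6 groups: cortical organoids grown from CDYL +/+ (H9) and CDYL -/- human embryonic stem cells, collected at day 30 and at day 80, and E15.5 mouse cortex from control embryos and embryos carrying Emx1-cre and the loxP-flanked Cdyl allele. Per the submitters' processing notes, reads were handled with fastp, HISAT2 and StringTie on the hg38 build, with no versions given and with the same text for human and mouse libraries. Per the labels, RNA was extracted with TRIzol and libraries were made with a stranded Illumina mRNA kit. The authors gave 1 value per gene and library in TPM, a transcript abundance scaled to a fixed total per library; the table headers name no unit, and TPM was inferred from the column sums and decimals. FPKM values would differ from these by 1 factor per library and were not excluded for the human table.

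The human table used here held 15304 genes, of which 15289 carried a symbol and 15291 were found in GENCODE release 29, and its values summed to between 54.4% and 56.9% of the nominal TPM total per library. The mouse table held 55414 genes under Ensembl identifiers without symbols, with sums between 98.8% and 99.2% of that total. Identifiers were not translated to symbols without a table pairing them, so gene lists, the levels of Cdyl and Nnat in mouse cortex, and the overlap between organoids and mouse cortex were not analysed here. The human CDYL transcript was not analysed here either, so the CDYL -/- label was not checked at its own transcript. TPM keep no read totals, so the depth per library is unknown and no counting intervals are given. A change on log2(TPM + 1) understates the ratio of genes near or under 1 TPM.

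Values were transformed as log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the fitted libraries were tested: 10698 in the organoids and 14787 in the mouse cortex. The 12 organoid libraries were fitted together in limma 3.58.1 (R 4.3.3) with a mean for each combination of genotype and day (8 residual degrees of freedom), and moderated statistics were computed by eBayes with a variance trend and robust settings. From this fit came CDYL -/- minus control at day 30 and at day 80, the difference between these 2 contrasts, and day 80 minus day 30 in control organoids. The 6 mouse libraries were fitted alone (4 residual degrees of freedom). P values are 2-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05 and no limit on the fold. The fit was tested on simulated data with 100 changed genes per size: 67% to 83% of genes changed by 1 on the log2 scale and 93% to 95% of genes changed by 2 were recovered, and 3.01% to 7.37% of calls were false. The simulated noise was normal, independent between genes and equal in all groups, as the fit assumes. These shares therefore check the fit under its own assumptions and do not give the share of false calls among the real libraries.

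Before the data were examined, 36 gene lists were fixed that cover regional identity, cell types and pathways, and 34 of them had members among the genes tested in organoids; many lists were only partly covered. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Tests with an estimated correlation and with fry were run as alternatives; fry asks whether a list moves one way on balance and does not compare it with other genes. With the estimated correlation none of the 4, 9, 5 and 15 lists called at day 30, at day 80, between the days and over time passed, and those values stand beside the lists. The rule for named genes was also fixed then: NNAT and a short set of regional, cell type and chromatin genes; the 8 genes with the largest and the 8 with the smallest change among called genes with separate groups and a mean of at least 5 TPM in the higher group; and up to 4 called members of each list, or 2 members given as values for a list with none. A gene outside this rule is named with the remark that it was chosen after its values were seen. The text names part of the genes the rule gives, and that part was picked after their values and their results with a library left out had been seen. A first pick had favoured genes whose calls held; genes whose calls were lost, and REST and EZH2, were then put back. The counts of results that depend on the processing therefore cover the tested genes under the rule, named in the text or not, apart from a few genes that are not reported here: 464 gene results, of which 369 were called, 268 of them in every fit with 1 library left out and 101 not.

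Overlap between days was tested with Fisher's exact test across genes, which are not independent replicates. Alternatives fixed in advance were another low-value filter or none, median-ratio scaling, limma without the trend, a pseudocount of 0.1, array weights, a limit of 1 on log2, the replicate number as a block, only the 6 libraries compared, and each library left out in turn. For the list tests and NNAT, the fit to only the 6 libraries compared was added after seeing the data. Fits without day 80 control library 3, or without 3 control libraries of mixed lineage (day 30 replicate 1 and day 80 replicates 1 and 3), were added after seeing the data. These 3 held the highest AFP, MYOG and POU5F1 levels among the controls, but muscle transcripts were also present in day 80 control replicate 2, which stayed in that fit. No CDYL -/- library was left out in these fits, although POU5F1 lay at 120 and 69.9 TPM in CDYL -/- replicates 1 and 3 of day 30.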

Results

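Transcript levels were measured in cortical organoids, which are aggregates of neural tissue grown from pluripotent cells, and in embryonic mouse cortex. The organoids came from the human embryonic stem cell line H9 (CDYL +/+, control) and from CDYL -/- cells, with 3 libraries per genotype at day 30 and 3 at day 80. The mouse cortex was taken at E15.5 from 3 control embryos and 3 embryos in which Emx1-cre, active in dorsal forebrain progenitors, recombines a loxP-flanked Cdyl allele. CDYL encodes a chromodomain protein known to act as a transcriptional corepressor. All values are TPM, whose read depth is unknown. Day separated the organoid libraries along the first principal component, which held 64.8% of the variance. Replicates of a group correlated with Pearson's r between 0.924 (control, day 80) and 0.989 (control, day 30) across genes, which are not independent replicates.

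Several organoid libraries carried transcripts of other lineages. POU5F1, the pluripotency factor OCT4, stood at 436 TPM in day 80 control replicate 3, against 0.25 and 0.45 TPM in the other controls of that day, and at 120, 6.85 and 69.9 TPM in the CDYL -/- libraries of day 30. AFP, which encodes the fetal liver and yolk sac protein alpha-fetoprotein, reached 760 TPM in day 30 control replicate 1 and 232 TPM in day 80 control replicate 3. MYOG, a skeletal muscle transcription factor gene, reached 255 TPM in day 80 control replicate 1 and 31.2 TPM in replicate 2. AFP and MYOG were chosen after their values were seen.

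**Figure D1:**
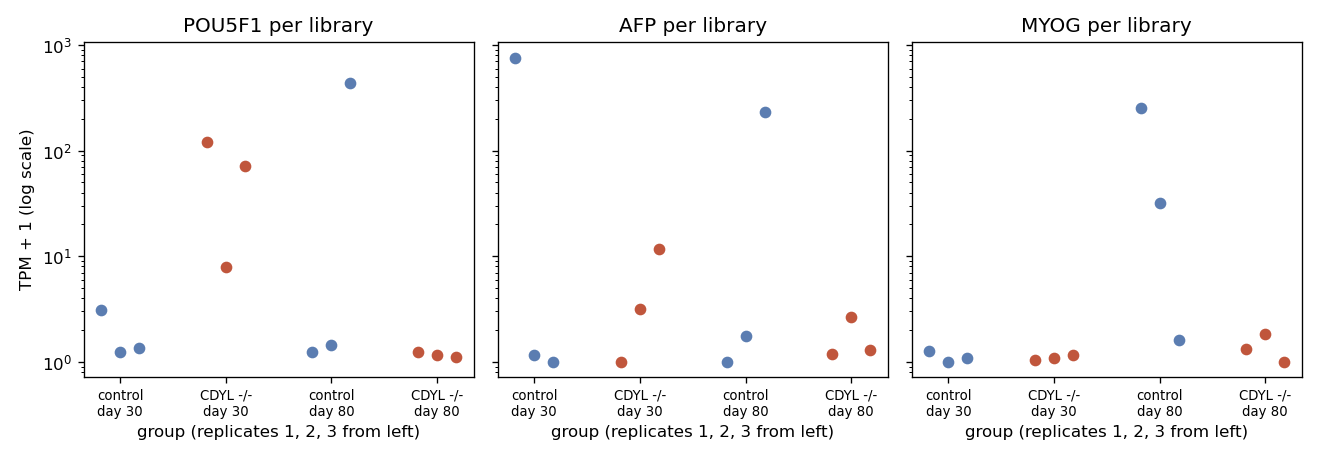
POU5F1, AFP and MYOG in each organoid library, as TPM + 1 on a log axis; every point is 1 library, and the 4 groups hold 3 each. POU5F1 reached 436 TPM in day 80 control replicate 3, AFP 760 TPM in day 30 control replicate 1, and MYOG 255 TPM in day 80 control replicate 1.

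The comparison of genotypes at day 30 asked how the absence of CDYL changes organoids while regional identities are laid down, with NNAT as the gene of interest named by the series. NNAT, an imprinted gene that encodes a small proteolipid of the endoplasmic reticulum, rose from 3.64 ± 1.23 TPM in control to 832 ± 188 TPM in CDYL -/- organoids (mean ± SD, n = 3), a log2 change of 7.49 ± 0.20 (SE; adjusted p = 7.8e-10). Dorsal telencephalic genes fell: OTX1, a homeobox gene of the anterior brain, by 3.15 on the log2 scale (11.4 ± 4.55 to 0.34 ± 0.147 TPM, adjusted p = 1.5e-04) and EMX1, which marks the cortical primordium, by 2.20 (6.47 ± 3.49 to 0.55 ± 0.477 TPM, adjusted p = 0.0036). BCL11A, a zinc finger gene of cortical neurons, fell by 1.68 (adjusted p = 0.0058). EMX2, EOMES and LHX2, which specify cortex and its intermediate progenitors, also fell, by 2.06, 2.22 and 1.69. Each of these 3 calls was lost when control replicate 1 or 3 or CDYL -/- replicate 1 or 3 was left out, with adjusted p of up to 0.0938 (EMX2), 0.129 (EOMES) and 0.0890 (LHX2), and with the replicate number as a block (0.0950, 0.102 and 0.0679). NEUROG2, a proneural gene of cortical progenitors, fell by 1.63, a call lost without control replicate 3 (0.0560) or CDYL -/- replicate 1 (0.0551). FEZF2, a gene of deep layer neurons, missed the threshold at -2.08 (adjusted p = 0.0512) and passed without CDYL -/- replicate 2 (0.0153). Of the 21 dorsal telencephalic genes tested, 8 fell, 1 rose and 12 were not called (13 lower and 1 higher adjusted over the list alone), with a camera adjusted p of 2.0e-04 and an adjusted p = 0.997 with an estimated correlation.

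In the hg38 build NNAT lies on chromosome 20 from 37521206 to 37523693 on the plus strand, inside the span of BLCAP on the other strand (37492472 to 37527931). BLCAP, itself imprinted in brain, lay between 127 and 147 TPM in the day 30 controls and between 87.8 and 99 TPM in CDYL -/- organoids and was not called (adjusted p = 0.084). At day 80 it lay between 132 and 234 TPM in control and between 204 and 281 TPM in CDYL -/- libraries (adjusted p = 0.14). NNAT lay between 1503 and 1800 TPM in the CDYL -/- libraries of day 80.

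**Figure D2:**
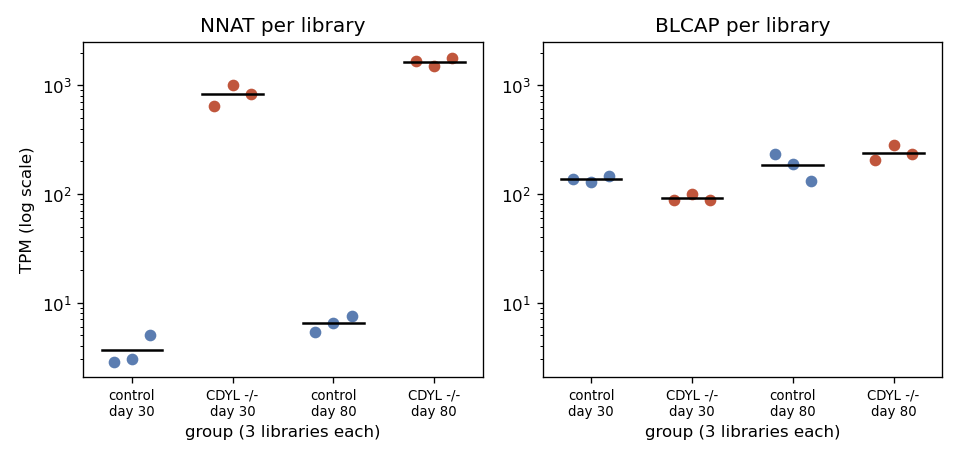
NNAT and the overlapping gene BLCAP in each organoid library, in TPM on a log axis; points are libraries, and lines are means of the 3 libraries of a group. NNAT lies under 10 TPM in all 6 control libraries and above 600 TPM in all 6 CDYL -/- libraries, from 640 to 1800 TPM.

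Single genes of other brain regions rose or fell at day 30. DBX1, a homeobox gene of progenitor domains in the diencephalon, hindbrain and spinal cord, went from 1.03 ± 0.467 to 167 ± 59.7 TPM (log2 change 6.33 ± 0.46, adjusted p = 1.4e-05), and its relative DBX2 from 0.0267 ± 0.0462 to 9.22 ± 4.01 TPM. FGF8, the signal of the midbrain-hindbrain organizer and the anterior neural ridge, rose by 3.43 ± 0.47 on the log2 scale. PAX2 and PAX8, which act at the midbrain-hindbrain boundary, rose by 3.20 and 1.89. NTN1, a floor plate guidance cue, rose by 3.53, POMC, the precursor of hypothalamic melanocortins, by 2.97, and NEUROG3, a proneural gene used in the hypothalamus, by 2.39. PENK, which encodes proenkephalin, and SFRP2, a secreted WNT antagonist, rose by 2.72 and 2.05. ATOH1, which specifies rhombic lip derivatives, fell by 3.09, LHX9, a gene of the thalamus and dorsal midbrain, by 3.28, and MIR9-1HG, the host transcript of a neural microRNA, by 4.97 (147 ± 41.4 to 4.39 ± 3.11 TPM). The netrin receptor genes DCC and UNC5C fell by 1.5 and 1.42. HOXA2 and HOXB1, genes of the hindbrain segments, rose by 2.08 and 2.67, and HES3, a NOTCH effector gene of the midbrain-hindbrain boundary, rose by 3.85, while PAX3, a gene of the dorsal neural tube and neural crest, fell by 1.52. Single libraries decided 3 of these calls. HOXB1 missed the threshold without control replicate 1 (0.0604) or 2 (0.0899) or CDYL -/- replicate 1 (0.0909) or 2 (0.0817). HES3 and PAX3 missed it whichever of the 6 libraries was left out, with adjusted p of up to 0.0884 and 0.117. With a pseudocount of 0.1 the calls of FGF8, POMC, HOXA2, HOXB1 and HES3 were lost (adjusted p = 0.0520, 0.0511, 0.0576, 0.0965 and 0.0797). Of 12 diencephalic genes 4 rose, 3 fell and 5 were not called (5 higher and 3 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.348). Of 26 midbrain, hindbrain and floor plate genes tested, 6 rose, 2 fell and 18 were not called (8 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.049, adjusted p = 0.997 with an estimated correlation). That list missed the threshold without control replicate 1 (0.0537), control replicate 3 (0.133) or CDYL -/- replicate 2 (0.0662), without day 80 control replicate 3 (0.0749) and with median-ratio scaling (0.0583). Of 27 genes of the HOX clusters, which pattern hindbrain and spinal cord, 2 rose, 0 fell and 25 were not called (2 higher adjusted over the list alone; camera adjusted p = 0.042, adjusted p = 0.997 with an estimated correlation). The HOX list missed the threshold without control replicate 1 (0.178), control replicate 2 (0.159), CDYL -/- replicate 2 (0.611) or day 80 control replicate 3 (0.0633).

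Pluripotency genes stood higher in the CDYL -/- libraries of day 30. LIN28A, an RNA-binding protein gene of pluripotent and early neural cells, was at 147 ± 65.2 TPM against 7.18 ± 6.26 TPM in control, and POU5F1 at 120, 6.85 and 69.9 TPM against at most 2.11 TPM. Neither passed in the fit of all 12 libraries (adjusted p = 0.175 and 0.230), and both passed without day 80 control replicate 3 (adjusted p = 3.0e-04 and 0.0062). Of 11 pluripotency genes 0 were called, over all genes or adjusted over the list alone, although their median log2 change was 1.48 (camera adjusted p = 0.017, adjusted p = 0.997 with an estimated correlation; 0.0689 without CDYL -/- replicate 1). The progenitor gene SOX2 (log2 change 0.05), PAX6 (0.46), OTX2 (-0.61), the cycling gene MKI67 (-0.40), EN1 (-1.66), DLX2 (-0.65), BDNF (0.14), RHOA (-0.05), TTR (-2.30), the neuronal gene repressor REST (0.52) and the PRC2 methyltransferase gene EZH2 (-0.27) did not pass. BCL11B, at -0.74, missed the threshold (adjusted p = 0.083).

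In all, 373 genes rose and 250 fell of 10698 tested at day 30 in limma. The groups did not overlap for 34.2% of genes tested, against 10% by chance. The count of 623 fell to 328 without control replicate 2, 340 without control replicate 3, 315 without CDYL -/- replicate 1, 370 without CDYL -/- replicate 2 and 386 without CDYL -/- replicate 3; the direction of every change is also that of 1 CDYL -/- line against 1 control line.

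The comparison at day 80 asked the same question in organoids that had formed neurons. NNAT stood at 1657 ± 149 TPM against 6.44 ± 1.05 TPM in control (n = 3), a log2 change of 7.81 ± 0.20 (adjusted p = 4.8e-10). Dorsal telencephalic genes fell. EMX1 fell by 4.65 ± 0.36 on the log2 scale (30.0 ± 10.6 to 0.21 ± 0.251 TPM), EOMES, the gene of intermediate progenitors, by 4.56, EMX2 by 4.25 and LHX2 by 3.56 (82.1 ± 11.7 to 6.16 ± 2.06 TPM). NEUROD6 and NEUROD2, expressed in young cortical excitatory neurons, fell by 3.21 and 2.36. FEZF2 and BCL11B, which specify subcerebral projection neurons of the deep layers, fell by 3.89 and 2.39. PAX6, a radial glial gene, fell by 1.62 (adjusted p = 0.016) but missed the threshold without control replicate 1 (0.0520) or control replicate 3 (0.0509). NEUROG2 fell by 2.71. CUX2, an upper layer gene also used outside the cortex, rose by 1.02. Of 21 dorsal telencephalic genes, 17 fell, 1 rose and 3 were not called (17 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.5e-12, adjusted p = 0.726 with an estimated correlation), with a median of -2.71.

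**Figure D3:**
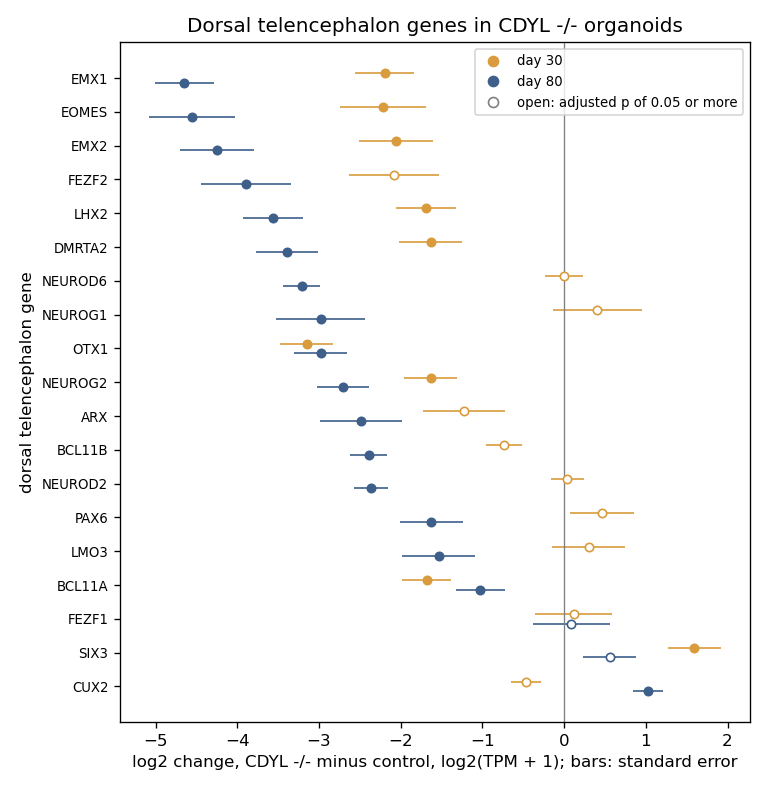
Log2 change in CDYL -/- against control organoids for dorsal telencephalic genes tested and reported, on log2(TPM + 1); points are estimates from 3 libraries per group at day 30 and at day 80, bars are standard errors, and open points did not pass. At day 80, EMX1 was lowest at -4.65, and CUX2 rose by 1.02.

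Posterior genes and the hypothalamic gene OTP stood higher at day 80. OTP, a homeobox gene of hypothalamic neuroendocrine neurons, rose by 4.40 ± 0.86 on the log2 scale (1.29 ± 0.735 to 75.1 ± 74.2 TPM, adjusted p = 0.0069). HOXB5, a hindbrain and spinal cord gene, rose by 2.47 ± 0.46 (0.617 ± 0.901 to 7.14 ± 0.607 TPM), and PAX2, PAX5, PAX8 and IRX3, genes of the midbrain-hindbrain boundary and posterior neural tube, rose by 2.66, 1.83, 2.47 and 1.90. HOXB8, HOXB9 and HOXC8, genes of the spinal cord, rose by 3.88, 3.92 and 2.13. The call of HOXC8 was lost without CDYL -/- replicate 2 (0.0573) and with a pseudocount of 0.1 (0.0582), and that of HOXB9 without control replicate 1 (0.107) or 2 (0.101) or CDYL -/- replicate 1 (0.0739), 2 (0.0804) or 3 (0.0788). Of 27 HOX genes 14 rose, 0 fell and 13 were not called (15 higher adjusted over the list alone; camera adjusted p = 4.3e-06, adjusted p = 0.762 with an estimated correlation). Of 26 midbrain, hindbrain and floor plate genes, 8 rose, 0 fell and 18 were not called (8 higher adjusted over the list alone; camera adjusted p = 0.0093, adjusted p = 0.726 with an estimated correlation). This list missed the threshold without control replicate 1, which carried MYOG (0.0634). Of 12 diencephalic genes 3 rose, 2 fell and 7 were not called, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.740). POMC (log2 change -0.19), EN1 (-0.60), OTX2 (-0.47) and the ventral telencephalic gene DLX2 (0.25) did not pass.

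Neuronal genes rose and growth genes fell at day 80. RPH3A, which encodes a synaptic vesicle effector, rose by 3.33 ± 0.30 on the log2 scale (4.09 ± 1.27 to 51.2 ± 16.9 TPM), and the vesicle protein genes SYN1, SYN2, SV2A and SV2B by 1.13, 1.04, 0.90 and 1.65. MAPT, which encodes tau, rose by 1.03, UNC5C by 0.99, CHGB, a secretory granule gene, by 1.35, and the adhesion and guidance genes L1CAM, SLIT1 and EPHB1 by 1.20, 1.17 and 1.07. STMN1, a microtubule regulator gene, rose by 0.43, a call lost without control replicate 1 (0.0542) or CDYL -/- replicate 2 (0.0661). REST, which encodes a repressor of neuronal genes, fell by 0.79 (adjusted p = 0.0195), a call lost without control replicate 1 (0.0556) or 3 (0.0623) or CDYL -/- replicate 2 (0.0638) or 3 (0.0648). EZH2 fell by 0.52 (adjusted p = 0.0177), a call lost without CDYL -/- replicate 2 (0.0638). The synapse and excitability list had 12 of 18 members higher, 0 lower and 6 not called (14 higher adjusted over the list alone; camera adjusted p = 4.3e-06, adjusted p = 0.726 with an estimated correlation). The pan-neuronal list had 7 of 12 members higher, 0 lower and 5 not called (9 higher adjusted over the list alone; camera adjusted p = 7.2e-05, adjusted p = 0.726 with an estimated correlation). Of 21 neurotrophin and axon guidance genes 7 rose, 1 fell and 13 were not called (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0049, adjusted p = 0.726 with an estimated correlation); their members BDNF (log2 change 0.34) and RHOA (-0.19) did not pass. The ribosomal protein genes RPL19 and RPS18 fell by 0.63 and 0.83, and NUSAP1, a mitotic spindle gene, by 0.94. HMGB2, a chromatin gene of cycling cells, fell by 0.99, a call lost without CDYL -/- replicate 2 (0.0525). The ribosomal protein list had 0 of 12 members higher, 8 lower and 4 not called (11 lower adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.726 with an estimated correlation), and the proliferation list 0 of 27 higher, 4 lower and 23 not called (12 lower adjusted over the list alone; camera adjusted p = 1.1e-04, adjusted p = 0.770 with an estimated correlation). Control replicate 3, with 436 TPM of POU5F1, is part of each of these contrasts. Without it the list medians went from 0.77 to 0.71 (synapse), 0.82 to 0.59 (pan-neuronal), -0.59 to -0.34 (ribosomal) and -0.55 to -0.27 (proliferation).

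**Figure D4:**
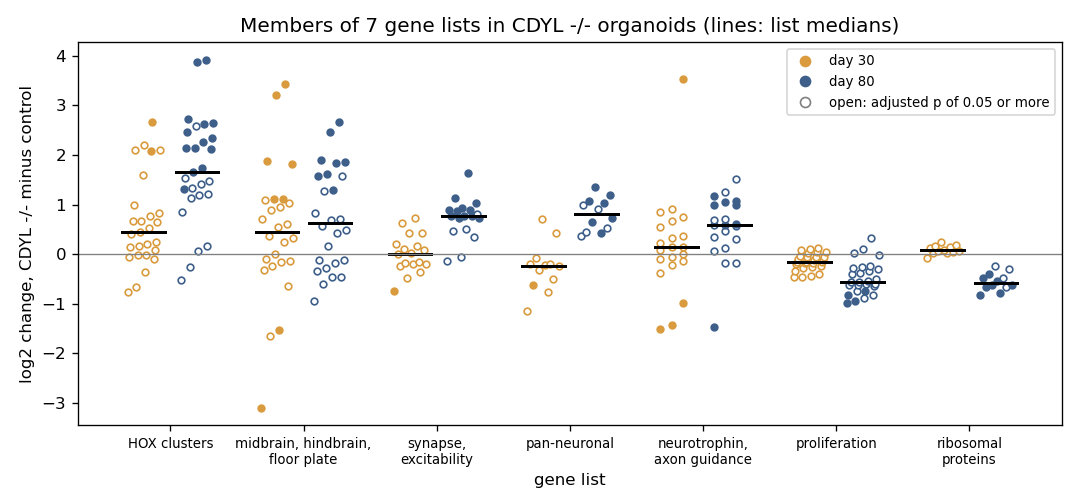
Log2 change in CDYL -/- against control organoids for the tested members of 7 gene lists at day 30 and day 80, on log2(TPM + 1); points are genes, open points did not pass, and lines are list medians. At day 80 the medians were 1.65 for HOX clusters, 0.77 for synapse and excitability, -0.55 for proliferation and -0.59 for ribosomal proteins.

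Of 17 imprinted genes tested at day 80, 4 rose, among them NNAT, NDN (log2 change 0.62), MAGEL2 (0.82) and NAP1L5 (0.77), 1 fell and 12 were not called (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.762 with an estimated correlation). This list missed the threshold without control replicate 3 (0.215) or CDYL -/- replicate 2 (0.0866). MAGEL2 missed it without CDYL -/- replicate 2 (0.0680) or 3 (0.0522), and NAP1L5 without CDYL -/- replicate 2 (0.0674). TNNT2, a troponin gene of heart muscle, fell by 4.70, a call lost without control replicate 1 (0.0613) or 2 (0.0503) or CDYL -/- replicate 1 (0.0535), 2 (0.0634) or 3 (0.0664). The transcript INS-IGF2, which spans the imprinted growth factor gene IGF2 and could not be told from it by position, fell by 5.36 (221 ± 118 to 3.79 ± 1.01 TPM). In day 80 control replicates 1, 2 and 3, TNNT2 lay at 287, 31.3 and 5.53 TPM and MYOG at 255, 31.2 and 0.59 TPM. INS-IGF2 lay at 274, 85.6 and 302 TPM in these libraries. In the day 30 controls it lay at 169 TPM in replicate 1, which carried AFP, and at 11.03 and 14.15 TPM in replicates 2 and 3. ZNF667-AS1, an antisense transcript at a zinc finger gene, fell by 4.05 at day 30 (17.1 ± 2.95 to 0.0867 ± 0.133 TPM) and by 4.36 at day 80, and ZNF506, a zinc finger gene, by 3.47 at day 30. Of the 34 lists tested at day 80, 9 passed. Among those that did not were intermediate progenitors (1 of 13 higher, 3 lower; camera adjusted p = 0.740), deep layer neurons (1 of 10 higher, 4 lower; 0.281), upper layer neurons (2 of 12 higher, 4 lower; 0.740), ventral telencephalon (2 of 12 higher, 1 lower; 0.369), radial glia (1 of 16 higher, 3 lower; 0.999, median 0.13 with the test pointing down) and chromatin partners of CDYL (1 of 18 higher, 4 lower; 0.0511). Adjusted over the list alone, 2 intermediate progenitor genes, 2 deep layer genes, 5 upper layer genes, 3 ventral telencephalic genes and 2 chromatin partners were higher, with the other counts the same. For intermediate progenitors and upper layer neurons the medians (0.11 and 0.10) were above 0 while the means (-0.39 and -0.47) and the tests pointed down. SOX2 (log2 change 0.15), MKI67 (-0.25) and TTR (-1.68) did not pass.

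In all, 1128 genes rose and 814 fell of 10698 tested at day 80 in limma. With only the 6 libraries compared, more genes were called at day 30 than at day 80. The counts therefore do not rank the 2 days. The groups did not overlap for 31.3% of genes, against 10% by chance. The count of 1942 fell to 1086 without CDYL -/- replicate 2 and to 465 without the 3 control libraries of mixed lineage. That fit left 1 control library of day 80, replicate 2, which itself held 31.2 TPM of MYOG and whose spread was assumed to equal that of the other groups. In that fit EMX1, EMX2, EOMES, LHX2 and NNAT passed, while PAX6 (adjusted p = 0.264), OTP (0.142), SYN1 (0.16), SYN2 (0.0909), SV2A (0.18), MAPT (0.192), UNC5C (0.169), NDN (0.237), MAGEL2 (0.352), NAP1L5 (0.290), REST (0.439), EZH2 (0.345), RPS18 (0.0819), CHGB (0.130), L1CAM (0.142), SLIT1 (0.190), EPHB1 (0.0569), STMN1 (0.0913), HOXB9 (0.0513), HMGB2 (0.199), NUSAP1 (0.112) and the midbrain (0.445), proliferation (0.380) and imprinted (0.353) lists did not.

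The difference between the genotype contrasts of the 2 days asked which changes grew or shrank as the organoids matured. NNAT did not differ between the days (log2 difference 0.31 ± 0.28, adjusted p = 0.50). EMX1, which fell at both days, fell further at day 80, by a log2 difference of -2.45 ± 0.51 (adjusted p = 0.0148), and BCL11B, not called at day 30, differed by -1.66. NEUROD2 and NEUROD6 (-2.40 and -3.21) were listed at or near 0 TPM in all 6 libraries of day 30, so that their differences restate the change at day 80. CUX2 differed by 1.49 in the other direction. The early rises of DBX1 (-4.28), FGF8 (-3.62), POMC (-3.16) and SFRP1, another secreted WNT antagonist (-4.89), were smaller or turned at day 80. FGF8 and POMC lay at no more than 1.66 and 1.28 TPM in any library of day 80, so that their differences restate the change at day 30. NMRK2, a nicotinamide riboside kinase gene, differed by -6.03. MIR9-1HG (5.72), MAB21L1, a developmental regulator of eye and brain (4.39), PRAME, a cancer and germline antigen gene (3.8), TRH, the thyrotropin-releasing hormone gene (3.53), ATOH1 (2.98), and the netrin receptor genes UNC5C (2.41) and DCC (2.22) moved up between the days. ATOH1 lay at no more than 1.06 TPM in any library of day 80, so that its difference restates the fall at day 30. The neuronal genes MAPT (1.79) and STMN1 (1.05) and the imprinted gene NDN (1.12) moved up and RPL19 (-0.66) moved down.

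Other calls between the days rested on single libraries. PAX6 (log2 difference -2.09, adjusted p = 0.0408) was lost whichever library was left out except CDYL -/- replicate 3 of day 30, control replicate 1 of day 30 and control replicate 2 of day 80, with adjusted p of up to 0.0971, and LHX2 (-1.87, adjusted p = 0.0474) with the same exceptions, up to 0.107. HOXB1 (-3.18) was lost without any library of day 30 except CDYL -/- replicate 3, or without any CDYL -/- library of day 80, up to 0.0902. HOXB1 lay at no more than 2.05 TPM in any library of day 80, so that its difference mainly restates the change at day 30. BLCAP (0.98), which overlaps NNAT, was lost without any library of day 30 or CDYL -/- replicate 2 or 3 of day 80, up to 0.0844. SV2B (1.57) was lost without any library of day 30 or CDYL -/- replicate 1 or 2 of day 80, up to 0.0781, and SYN2 (1.03) whichever library was left out except control replicate 1 of day 30, CDYL -/- replicate 1 of day 80 and control replicate 2 of day 80, up to 0.0861. MAGEL2 (1.20) was lost without any library of day 30 except CDYL -/- replicate 2, or without CDYL -/- replicate 2 or 3 of day 80, up to 0.0643. STMN2, a growth cone gene (1.58), was lost without control replicate 2 or 3 of day 30, CDYL -/- replicate 1 or 2 of day 80, or control replicate 1 or 3 of day 80, up to 0.0844. GAP43, a growth cone gene (2.14), and PAX3 (2.24) were lost without CDYL -/- replicate 1 or control replicate 2 or 3 of day 30, and GAP43 also without CDYL -/- replicate 2 of day 80 and PAX3 without CDYL -/- replicate 2 of day 30, up to 0.0621 and 0.0613. REST (-1.31, adjusted p = 0.018) was lost without CDYL -/- replicate 1 (0.0505) or control replicate 2 (0.0537) of day 30, and RPS18 (-1.0) and the ephrin receptor gene EPHA7 (-2.14) without control replicate 2 of day 30 (0.0537 and 0.0548).

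Of 21 dorsal telencephalic genes, 7 had a lower difference, 1 a higher and 13 were not called (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.1e-05). The pan-neuronal list had 4 of 12 higher, 0 lower and 8 not called (9 higher adjusted over the list alone; 2.7e-05), the synapse list 7 of 18 higher, 0 lower and 11 not called (9 higher adjusted over the list alone; 1.9e-04), the ribosomal list 0 of 12 higher, 4 lower and 8 not called (9 lower adjusted over the list alone; 4.3e-05), and the pluripotency list 0 of 11 called either way, with a median of -3.11 (0.00135). Each of these 5 lists had an adjusted p = 0.817 with an estimated correlation. In the pluripotency list, POU5F1 and LIN28A lay at 436 and 206 TPM in control replicate 3 of day 80. They lay at no more than 0.45 and 0.13 TPM in the other controls of that day. For these 2 genes the day 80 contrast restates that library, and the list median without it is not given here. EMX2 (log2 difference -2.19, adjusted p = 0.053) and EOMES (-2.34, 0.0714) missed the threshold. EMX2 passed without CDYL -/- replicate 1 of day 80 (0.0315) or control replicate 1 of day 30 (0.0391), and EOMES without control replicate 2 of day 80 (0.0371). SOX2 (log2 difference 0.11), OTX2 (0.14), TTR (0.63), MKI67 (0.14), DLX2 (0.90), BDNF (0.20), RHOA (-0.14), EZH2 (-0.25), EN1 (1.06) and POU5F1 (-7.55, adjusted p = 0.11) did not pass, though EN1 passed without control replicate 2 of day 80 (0.0169) and POU5F1 without control replicate 3 of day 80 (0.0393). With a pseudocount of 0.1 the calls of BCL11B (adjusted p = 0.529), FGF8 (0.0987), POMC (0.0925) and ATOH1 (0.0554) were lost, and RPL19 (0.0866), PAX6 (0.121), LHX2 (0.127), REST (0.151), SYN2 (0.151) and STMN2 (0.175) were among those lost without the 3 control libraries of mixed lineage.

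In all, the genotype difference differed between the days for 944 genes in limma, 571 upward and 373 downward. The count fell to 429 or 608 without CDYL -/- replicate 1 or 2 of day 30, to 623 without replicate 3, to 524 without CDYL -/- replicate 2 of day 80, and to 386 or 425 without control replicate 2 or 3 of day 30, and it rose to 1501 without control replicate 2 of day 80. Of the genes called at both days, 224 of 288 went the same way: 161 rose at both, against 39.3 by chance (odds ratio 7.35, Fisher's exact p = 3.2e-62 across genes), and 63 fell at both, against 19 by chance (odds ratio 4.35, p = 5.0e-18). NNAT, PAX2 and PAX8 were among the genes that rose at both days, and EMX1, OTX1 and ZNF667-AS1 among those that fell. The number falling at both days was 41 without control replicate 3 of day 30 and 40 without CDYL -/- replicate 1 of day 30.

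The comparison of day 80 with day 30 in control organoids gave the course of maturation against which the genotypes can be read. Cortical neuron genes rose: NEUROD2 from 0.0167 ± 0.00577 to 59.1 ± 19.4 TPM and BCL11B from 0.827 ± 0.0987 to 19.4 ± 6.71 TPM (mean ± SD, n = 3; log2 change 3.44 ± 0.22), while NEUROD6 was listed at 0 in all day 30 libraries and stood at 140 ± 39.1 TPM at day 80. SOX11, a gene of immature neurons chosen after its values were seen, was likewise listed at 0 in all 6 libraries of day 30 and lay between 67.1 and 84.1 TPM at day 80, and such zeros can be failed estimates. EMX1 rose by 2.12, PAX6 by 1.68 and BDNF, a neurotrophin gene, by 1.73. GFAP, the intermediate filament gene of astrocytes and radial glia, rose by 6.61 ± 0.67, and HOPX and PTN, genes of outer radial glia, by 4.96 and 2.31. SYN1, CAMK2B and the secretogranin gene SCG2, genes of synapse and secretion, rose by 2.44, 2.86 and 4.11. Large changes were also seen in 3 single genes known to be induced by interferon, a group with no fixed list and no test. IFIT2 rose by 7.58 ± 0.23 and ISG15 by 6.63 ± 0.27 (21.0 ± 2.40 to 2203 ± 503 TPM). OASL was listed at 0 in the day 30 control libraries and at 299 ± 175 TPM at day 80. The chemokine genes CXCL10 and CCL5 rose by 7.03 and 7.02. NNAT rose from 3.64 ± 1.23 to 6.44 ± 1.05 TPM (log2 change 0.70, adjusted p = 0.0085), a call lost with median-ratio scaling (0.195), with array weights (0.0513) and without the 3 libraries of mixed lineage (0.0971). REST rose by 0.65 (adjusted p = 0.0153), a call lost without control replicate 2 of day 30 (0.0586) or control replicate 3 of day 80 (0.0563) and with median-ratio scaling (0.346). SOX2 rose by 0.35 (adjusted p = 0.0484), a call lost without control replicate 1 (0.152), 2 (0.0641) or 3 (0.0789) of day 30 or control replicate 1 (0.0975) or 2 (0.198) of day 80, and median-ratio scaling turned its sign (-0.11).

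Cycling genes fell with time. UBE2C, a mitotic ubiquitin ligase gene, fell by 1.67, MCM2, a replication licensing gene, by 1.48, TYMS by 1.30, MKI67 by 0.53 and EZH2, the methyltransferase of Polycomb complex PRC2, by 0.79. RPL10A, a ribosomal protein gene, fell by 1.35. RSPO1, a WNT agonist of the cortical hem, fell by 3.31, ATOH1 by 3.27, OLIG3, a dorsal hindbrain progenitor gene, by 3.20, FGF17 by 3.03 and PAX8 by 2.31. EMX2, OTX2, TTR, EN1, DLX2 and RHOA did not pass; OTX2 (log2 change -1.38) passed without control replicate 2 of day 30 (0.0173), EN1 (-0.83) without control replicate 2 of day 80 (0.00112) and RHOA (0.23) without control replicate 3 of day 80 (0.0417). The proliferation list had 0 of 27 members higher, 23 lower and 4 not called (23 lower adjusted over the list alone; camera adjusted p = 7.2e-19, adjusted p = 0.310 with an estimated correlation), and the ribosomal list 0 of 12 higher and 12 lower, also adjusted over the list alone (4.1e-15; adjusted p = 0.219 with an estimated correlation). All 18 synapse and excitability genes rose, also adjusted over the list alone (5.0e-05; adjusted p = 0.470 with an estimated correlation). Midbrain, hindbrain and floor plate genes had 3 of 26 higher, 11 lower and 12 not called (3 higher and 9 lower adjusted over the list alone; 2.5e-07; adjusted p = 0.219 with an estimated correlation).

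Stress and calcium genes rose in the same interval. ATF5 and TRIB3, targets of the integrated stress response, rose by 2.40 and 2.48, CAMK2D and the chaperone gene CALR by 1.85 and 0.92, VEGFA and PGK1, targets of hypoxia signalling, by 2.00 and 1.09. The stress list had 10 of 12 higher, 0 lower and 2 not called (10 higher adjusted over the list alone; camera adjusted p = 0.0054, adjusted p = 0.470 with an estimated correlation), the calcium handling list 11 of 12 higher, 0 lower and 1 not called (11 higher adjusted over the list alone; 0.0207; adjusted p = 0.470 with an estimated correlation). The hypoxia and glycolysis list had 12 of 14 higher, 1 lower and 1 not called (12 higher and 1 lower adjusted over the list alone; 0.0312; adjusted p = 0.574 with an estimated correlation; 0.0563 without control replicate 2 of day 80). Of 12 pan-neuronal genes 11 rose and 1 fell, also adjusted over the list alone (0.0312; adjusted p = 0.619 with an estimated correlation), a call lost without control replicate 1 of day 30 (0.0592) or control replicate 2 of day 80 (0.0517). Below the shift of all genes lay the HOX list (0 of 27 called; 8.5e-05), neural crest (0 of 15 higher, 3 lower; 0.00136), hem and choroid plexus (4 of 18 higher, 5 lower; 0.0054), diencephalon (3 of 12 higher, 4 lower; 0.0054), chromatin partners of CDYL (4 of 18 higher, 4 lower; 0.0035), SHH pathway (1 of 12 higher, 3 lower; 0.0190) and mesenchyme (1 of 10 higher, 2 lower; 0.0312), with an adjusted p between 0.219 and 0.470 with an estimated correlation. Adjusted over the list alone, these counts differed only for neural crest (1 lower) and for hem and choroid plexus (3 higher). In the last 3 of these lists the test pointed down while the mean (chromatin partners 0.01) or the median (SHH 0.07, mesenchyme 0.01) was above 0. The diencephalon list was lost without control replicate 3 of day 30 (0.0653), SHH without control replicate 1 of day 30 (0.0804), and mesenchyme without control replicate 1 of day 30 (0.0885) or control replicate 2 of day 80 (0.117). With median-ratio scaling the HOX (0.178), neural crest (0.0690), hem (0.280), diencephalon (0.293), SHH (0.116) and mesenchyme (0.397) lists were lost.

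In all, 5464 genes rose and 916 fell with time of 10698 tested in limma, and the groups did not overlap for 65.5% of genes, against 10% by chance. The median gene rose by 0.47 on the log2 scale, and median-ratio scaling, which brought that median to 0.06, called 2821 genes higher and 2343 lower.

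The mouse comparison asked what changes in E15.5 cortex when Cdyl is recombined in the Emx1 lineage. Genes are known here by identifier alone. ENSMUSG00000073067 rose from 0.817 ± 0.586 to 65.4 ± 15.4 TPM (n = 3; log2 change 5.21 ± 0.25, adjusted p = 1.2e-04), and ENSMUSG00000096729 was listed at 0 in control and stood at 31.6 ± 5.79 TPM in the knockout. ENSMUSG00000104961 and ENSMUSG00000103148 stood at 9.85 ± 4.55 and 8.22 ± 6.46 TPM in control and were listed at 0 in the knockout. Changes were small: the median size among called genes was 0.52 on the log2 scale, against 1.01 and 0.77 for organoids at day 30 and day 80, and 105 genes changed by at least 1. In limma 461 genes rose and 525 fell of 14787 tested, with 4413 at an unadjusted p under 0.05, and the groups did not overlap for 35.8% of genes, against 10% by chance. The count of 986 dropped to 18 without control replicate 1, 55 without control replicate 3, and 57, 9 and 166 without knockout replicates 1, 2 and 3, to 56 with no filter, to 77 without the variance trend and to 73 with the replicate number as a block.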

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

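The tests weighing day 80 control replicate 3 were chosen only after the result was seen, as was the choice of which genes the text names. The splits of libraries at day 30, at day 80, over time and in mouse cortex were also chosen only after the result was seen. The difference between the days was tested as set before the data were examined. The results in this part are here because the effect of genotype differed between day 30 and day 80 by a test of the difference itself. They cover the reported genes that the fixed rule names for that comparison and that passed, with genes named at either day added, 77 genes in all. Values are log2 differences of the genotype effect, day 80 minus day 30. The calls of 44 of these genes held in every fit with 1 of the 12 libraries left out, and those of 33 were lost in at least 1.

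Among calls that held with each library left out, the cortical genes EMX1 (-2.45), BCL11B (-1.66) and SOX5 (-1.56) moved down. SP8 (-1.55), from the ventral telencephalon list, moved down as well. BCL11B averaged under 1 TPM in the day 30 controls, where log2(TPM + 1) leaves little room for a fall, so that its value depends on the pseudocount. NEUROD2 (-2.40) and NEUROD6 (-3.21) passed too, but were listed at or near 0 TPM in all 6 libraries of day 30, possibly as failed estimates, so that their values restate the change at day 80 and do not test whether the effect of genotype differs. The patterning and secreted signal genes DBX1 (-4.28), DBX2 (-2.32), FGF8 (-3.62), POMC (-3.16), NEUROG3 (-1.40), SFRP1 (-4.89) and FZD8 (-2.19) also moved down, with EGR2 (-2.27), ERBB3 (-3.19), NMRK2 (-6.03), ORAI1 (-1.35), PLXND1 (-2.47), RPL19 (-0.66), SPHK1 (-3.65) and TCIM (-3.70). FGF8 and POMC lay at no more than 1.66 and 1.28 TPM in any library of day 80. Their values restate the change at day 30 and do not test whether the effect of genotype differs. The neuronal genes MAPT (1.79), STMN1 (1.05), RPH3A (2.88), NRXN2 (1.64), CBLN2 (3.21), CA10 (3.13) and TRH (3.53) moved up. So did the guidance genes DCC (2.22), UNC5C (2.41) and EPHA3 (1.61), the dorsal and posterior genes ATOH1 (2.98), GDF10 (1.92), RSPO1 (2.56) and TFAP2A (2.04), GSX1 (2.61) from the ventral telencephalon list, the imprinted genes NDN (1.12) and PEG10 (2.73), and CUX1 (0.66), CUX2 (1.49), MAB21L1 (4.39), MIR9-1HG (5.72), ORAI2 (1.15) and PRAME (3.8). ATOH1 lay at no more than 1.06 TPM in any library of day 80, so that its value restates the fall at day 30. A pseudocount of 0.1 ended the calls of BCL11B (adjusted p = 0.529), FGF8 (0.0987), POMC (0.0925), ATOH1 (0.0554) and NEUROG3 (0.204), and leaving out the 3 control libraries of mixed lineage ended those of DBX2 (0.0679) and RPL19 (0.0866).

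Calls lost with a library left out were those of PAX6 (-2.09), LHX2 (-1.87), SFRP2 (-1.49), SIX6 (-1.19), HOXB1 (-3.18), EPHA7 (-2.14), NEUROG1 (-3.39), REST (-1.31), HDAC1 (-1.02), RPL10A (-0.91), RPL11 (-0.78), RPS18 (-1.0), APELA (-3.62), BST2 (-4.49), PVALB (-2.46) and TPM2 (-4.07) among genes that moved down. Among genes that moved up they were those of BARHL1 (1.69), BLCAP (0.98), CAMK2B (1.01), FZD10 (3.40), GAP43 (2.14), GDF7 (1.34), MAGEL2 (1.20), NKD1 (1.05), PAX3 (2.24), RSPO2 (2.31), SP9 (1.27), STMN2 (1.58), SV2A (0.89), SV2B (1.57), SYN2 (1.03), TFAP2B (3.39) and WIZ (0.64). Their adjusted p reached at most 0.115. HOXB1, SIX6 and BARHL1 lay at no more than 2.05, 0.16 and 0.1 TPM in any library of day 80, so that their values mainly restate the change at day 30. Of the 77 calls, 31 were lost without control replicate 2 of day 30, 25 without control replicate 3 and 13 without control replicate 1 of that day, 25, 19 and 15 without CDYL -/- replicates 1, 2 and 3 of day 30, 10, 22 and 17 without CDYL -/- replicates 1, 2 and 3 of day 80, and 12, 1 and 8 without control replicates 1, 2 and 3 of day 80.

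The lists that differed between the days had median log2 differences of -1.76 (dorsal telencephalon), 0.88 (pan-neuronal), -3.11 (pluripotency), -0.67 (ribosomal proteins) and 0.68 (synapse and excitability). None of the 5 passed with an estimated correlation (adjusted p = 0.817). The pluripotency value includes day 80 control replicate 3, with POU5F1 at 436 TPM and LIN28A at 206 TPM. The other controls of that day held at most 0.45 and 0.13 TPM, and the list median without that library is not given here. Genotypes were reassigned within each day in 100 of 200 possible splits of the 12 libraries. Of these, 2 splits, the real one included, called at least the real 944 genes. Splits that mix the genotypes put the genotype difference shared by both days into the spread, which by itself lowers their counts. The splits therefore do not decide whether chance accounts for the differences between the days. The highest other split called 1203 genes; it exchanges the genotypes at one day, so that it measures the mean genotype difference, and the next highest called 243. At day 30, at day 80, over time and in mouse cortex, 1 of 10 splits, the real one, called as many genes (623, 1942, 6380 and 986), and the highest other split called 0, 1, 0 and 10; 10 splits are too few for a share under 0.05.

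The neuronal lists that were higher and the growth lists that were lower at day 80 were weighed against the POU5F1 level of 436 TPM in control replicate 3, since pluripotent cells in that library could lower neuronal and raise growth transcripts in the controls. Without it the median log2 change was 0.71 for synapse and excitability genes (0.77 with it, adjusted p = 1.5e-05 without), 0.59 for pan-neuronal genes (0.82, adjusted p = 2.4e-04) and -0.34 for ribosomal protein genes (-0.59, adjusted p = 2.4e-04), which argues against that library as the whole cause for these 3 lists. For proliferation genes the median went from -0.55 to -0.27 (adjusted p = 0.0326), under 0.5 of the value with it, so that the library may account for much of that change. Without control replicate 1 or 2, which carried 255 and 31.2 TPM of MYOG, all 4 lists passed, with medians of 0.79 and 0.82 (synapse), 0.88 and 0.93 (pan-neuronal), -0.61 and -0.67 (ribosomal) and -0.66 and -0.78 (proliferation), and muscle transcripts in both together stay open, as does a difference in the pace of maturation between the lines.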

How the results depend on the processing

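Fits without day 80 control library 3 or without the 3 control libraries of mixed lineage, and the fit of the list tests and NNAT to only the 6 libraries compared, were chosen only after the data were seen. NNAT kept its direction and its call at both days in every alternative run, at log2 changes from 7.34 to 7.70 (day 30) and 7.70 to 7.90 (day 80) with a library left out.

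The counts of genes moved by over 1.5 times as follows; fewer genes pass a fold limit by construction, and where other settings moved a count the cause was not tested. A limit of 1 on log2 gave 323 genes at day 30, 630 at day 80, 556 between the days, 2506 over time and 105 in mouse cortex, and 69 and 40 genes higher and lower at both days. Array weights gave 1887 at day 30, 1755 between the days and 1579 in mouse. Only the 6 libraries compared gave 1329 at day 30 and 741 at day 80, so that the order of the 2 days turned (623 and 1942 as reported). Day 30 without day 80 control library 3 gave 1012. Without the 3 control libraries of mixed lineage there were 465 genes at day 80, 428 between the days and 101 higher at both days. Mouse counts were 56 with no filter, 77 without the trend and 73 with the replicate block. With 1 library left out, counts lay between 315 and 483 at day 30, 1086 and 2409 at day 80, 386 and 1501 between the days, and 9 and 1002 in mouse, and between 40 and 62 for genes lower at both days.

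With an estimated correlation 0 lists passed in each of the 4 organoid comparisons (4, 9, 5 and 15 as reported), and with fry 0 at day 30 and 0 between the days. At day 30, 2 lists passed without day 80 control library 3 and 8 without the 3 control libraries of mixed lineage; between the days 11 passed without those 3, and 5 to 10 with 1 library left out.

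Over the tested genes that the fixed rule names, whether the text names them or not, 464 gene results gave 7502 values under the alternatives: 6670 kept their direction and side of the threshold, 723 lost their call, 108 gained one and 1 reversed, SOX2 over time, whose log2 change was -0.11 with median-ratio scaling. Which of these genes the text names was settled after such values had been seen, so no tally over the named genes alone is given. CDYL levels, mouse lists and the overlap of human and mouse calls were planned and not run. The depth behind TPM is unknown, so no limit from depth can be given.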

Other observations

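All tests in this part were chosen only after the result was seen. Each p here is 2-sided and across genes, which are not independent replicates.

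Genes of the X chromosome were over-represented among those higher in CDYL -/- organoids. At day 30, 58 of 357 tested X-linked genes rose (16.2%), against 314 of 10334 autosomal genes (3.04%; odds ratio 6.19, Fisher's exact p = 1.3e-23), and 4 fell. At day 80, 86 rose (24.1%), against 1040 autosomal genes (10.1%; odds ratio 2.84, Fisher's exact p = 1.0e-13), and 33 fell. The odds ratio at day 30 lay between 4.95 and 8.08 with 1 library of that day left out. Of the 58 genes, 40 (69.0%) rose at both days, against 120 of the 314 autosomal ones (38.2%; odds ratio 3.58, Fisher's exact p = 2.0e-05). Examples, chosen after their values were seen, are HPRT1, a purine salvage gene (log2 change 0.89 at day 30 and 1.12 at day 80), PHF6 (0.96 and 1.08), ANOS1 (2.44 and 2.27) and the apoptosis inhibitor gene XIAP (0.76 and 1.11).

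A gained X chromosome is argued against by the median log2 change of the tested X-linked genes, 0.0697 at day 30 and 0.17 at day 80, and a gain of its distal long arm by the 58.5% and 50.3% of 159 genes from 100 Mb on whose change was under 0.3. Changed cell makeup stays open. Among genes not called between the days in control organoids, 17 of 137 X-linked (12.4%) and 94 of 4176 autosomal genes (2.25%) rose at day 30 (odds ratio 6.15, Fisher's exact p = 4.5e-08). The excess was thus not confined to genes called over time in control organoids. Genes level over time can still differ between regions or cell types, so that these values do not decide about makeup. Changes of neighbouring X-linked genes went together at day 30, with a Spearman correlation of 0.37 against a highest value of 0.20 in 10000 shuffled orders, but at day 80 it was 0.11, inside the range of the shuffled orders (highest 0.19). Lost silencing of stretches of the chromosome in the CDYL -/- line may account for the day 30 values, and whether it comes from the loss of CDYL or from the line stays open with 1 line per genotype.

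The rise of NNAT was weighed in the same way. A gained chromosome segment is argued against by the median log2 change of 28 tested genes within 2 Mb, -0.13 at day 30 and -0.07 at day 80. Reads of BLCAP counted for NNAT are argued against by the sum of both genes, 6.54 and 9.90 times higher in CDYL -/- organoids. A general rise of imprinted genes is argued against by 1 of 17 tested imprinted genes, NNAT itself, called higher at both days. A difference between the lines other than the loss of CDYL cannot be told apart from it, since the labels name 1 line per genotype.

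In 11 genes all 6 libraries of one genotype lay under 1 TPM and all 6 of the other above 2 TPM. AMBN, IRAK4, PUS7L, ZNF229, ZNF506 and ZNF667-AS1 were under 1 TPM in CDYL -/- organoids, and LINC02693, TRIM61, ZNF248, ZNF680 and ENSG00000274847 in control. Zinc finger genes named ZNF or ZFP were 19 of the 224 genes changed the same way at both days (8.48%), against 477 of 10698 tested (4.46%; odds ratio 2.03, Fisher's exact p = 0.0076).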
